A study of Homo sapiens with 7 samples.

How the data were processed

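RNA was measured from HEK293 cells labelled with 100 µM 4SU for 1, 2, 4, 8, 12 or 24 h. There were 6 libraries of selected RNA and 1 of unselected RNA at 24 h, 1 library per group, and groups were taken from the sample titles. Per the labels, the RNA was polyadenylated, and fly S2 and HEK293 cells labelled for 24 h served to make labelled spike-ins. The labels also describe a yeast culture, whose role is not stated. The submitters' processing notes name bcl2fastq 2.17, FastQC 0.11.5, Trimmomatic 0.36, STAR 2.5.2a, HTSeq 0.6.1p2 and bedtools 2.26.0 with human, fly and yeast genome builds, without giving the role or order of each; strand handling is not given in the sources used here.

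The exon table holds raw read counts per gene as deposited by the authors, with 27172 human, 17024 fly and 5816 yeast genes and no normalization seen. Exonic counts summed to 6526613 to 12777210 per library. The intron table holds, per the file headers and values, the mean coverage signal per base of each intron, the fraction of its bases covered by at least 1 read and its length, for 132764 human introns. Another 7 columns of per-sample standard deviations were not used. A spreadsheet had turned 28 human gene names into dates; these genes stayed in the tests and are not named. The last 2 tables hold the authors' deposited half-lives, 1 by an intron-based normalization according to its name and 1 by a normalization that is not stated. Their fit procedure is not given in the sources used here, and the range of values fits hours.

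Introns were placed on GRCh38 with GENCODE release 29 by transcript, order and length, which worked for 91.9% of them. Of the placed introns 19.0% overlapped another gene and 37.5% an annotated exon. Gene coordinates are 1-based and from the same annotation. The intronic measure planned was a share of reads with a binomial interval, but the table gives base coverage, so intronic bases (coverage times length) per human exonic read were used instead, with no binomial interval. Its relation to time was tested with an exact two-sided permutation over 720 orders of the 6 libraries.

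The trend was fitted to the counts of the 6 selected libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr) in R 4.3.3, with log2 of the labelling hours as covariate and a Benjamini-Hochberg threshold of 0.05. In simulated data of 13248 genes, 200 of them changed, 20% of genes with a slope of 0.2 and 97% with a slope of 0.5 were recovered, and 6 unchanged genes were called. With so few changed genes the adjusted threshold is stricter than in the real data, where 5839 genes passed. These shares therefore do not give the share of real slopes missed. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 (preset correlation 0.01) on log2 CPM, and with fry as an alternative. Of 24 lists, 22 were tested. They covered immediate-early regulators, zinc-finger genes, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded mRNAs, glycolysis, histones, the proteasome, cholesterol, p53 targets, stress responses, G2/M, S phase, snoRNA hosts, nuclear long noncoding RNAs, splicing regulators, decay factors, translation factors, aminoacyl-tRNA synthetases, lysosomal genes, cytoskeleton and chaperones, and markers of blood, fibroblast and endothelial, and neuronal cells.

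Half-lives were fitted per gene with at least 50 counts over the 6 libraries and 1 in each. Exonic counts over total intronic signal were fitted to a rise from 0 to a plateau with residuals on the log scale, between bounds of 0.05 and 200 h, with 4 residual degrees of freedom and no correction for cell growth. In 2000 simulated genes the fit came within 1.5-fold of the truth for 69.5% of genes from 0.5 to 2 h, 81.0% from 2 to 8 h and 45.4% from 8 to 24 h. List medians were set against 10000 random lists of the same size matched on mean expression in 20 bins. The selected and unselected 24 h libraries were compared as log2 ratios of TMM-scaled counts with exact 95% counting intervals, among genes with a mean of at least 10 CPM. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Uridines were counted in the annotated transcript of each gene, available for 99.3% of these genes.

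Intron trends were fitted with limma on log2 of intronic bases plus 50, for introns with a mean of at least 500 bases. In simulated data of 23149 introns, 6% of introns with a slope of 0.3, 78% with 0.6, 98% with 1.2 and 100% with 2.4 were recovered, and 5 unchanged introns were called; the larger sizes were added when the smallest was not recovered.

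The comparisons, their tests, the gene lists, most alternatives and the rule for genes were fixed before the data were examined. Some alternatives, 3 of the 7 tests of explanations, part of the intron tests and the choice of introns came after. The rule named the 12 steepest genes in each direction with a mean of at least 10 CPM, the 8 shortest and 8 longest half-lives with at least 500 counts and a relative standard error under 0.25, the 8 highest and 8 lowest ratios, up to 4 members of each list by mean CPM, and MYC, FOS, JUN, ACTB and GAPDH. It left out pseudogenes, clone-based names, genes on the Y chromosome and genes of X inactivation. Some genes that met it are not reported here. Alternatives covered size factors from DESeq2 1.42.0, library totals, intronic signal or fly reads, the count filter, the DESeq2 and limma-voom tests, the time scale, other fits of the half-life and each time point left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.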

Results

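HEK293 cells, an established line of human embryonic kidney origin, were grown with 100 µM 4-thiouridine (4SU), a uridine analogue that is built into RNA made while it is present. Labelling lasted 1 h, 2 h, 4 h, 8 h, 12 h or 24 h, and the labelled RNA was selected before sequencing at each time. A further library was made from unselected RNA at 24 h. Each of these 7 groups held 1 library, so no difference between 2 time points had a replicate check. The stated aim of the series was to determine mRNA half-lives across the transcriptome. Reads came from human, fly and yeast RNA. Exonic counts per library ran from 6526613 to 12777210, of which 3443599 to 9581145 were human. Nothing in the labels said whether the time points came from separate cultures. The p-values below for single genes and introns therefore measure only the scatter of these 6 selected libraries around a fitted line. That scatter mixes library noise with curvature. Camera p-values with the preset correlation of 0.01 set the genes of a list against other genes and treat them as nearly independent. With an estimated correlation the lowest camera adjusted p was 0.289.

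Human RNA grew relative to fly RNA as labelling went on. The selected 1 h library held 0.964 human exonic reads per fly read, and the ratio was 2.59 at 2 h, 3.00 at 4 h, 6.60 at 8 h, 6.16 at 12 h and 10.8 at 24 h. The unselected library held 16.1. Human introns, which mark unspliced precursor RNA, made up a falling part of the human signal. Intronic bases per human exonic read were 21.4 at 1 h, 10.7 at 2 h, 6.71 at 4 h, 6.08 at 8 h, 5.06 at 12 h and 5.92 at 24 h, against 6.69 in the unselected library. The value at 1 h was 3.61 times that at 24 h. Spearman's rho with labelling time over the 6 selected libraries was -0.94 (exact two-sided permutation p = 0.0167), and Pearson's r with log2 hours was -0.84 (exact permutation p = 0.00556). Without the 1 h and 24 h libraries r was -0.94. Both tests were also run on other sets of introns, with a rho of -0.94 in each, and the p-values were not adjusted.

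**Figure D1:**
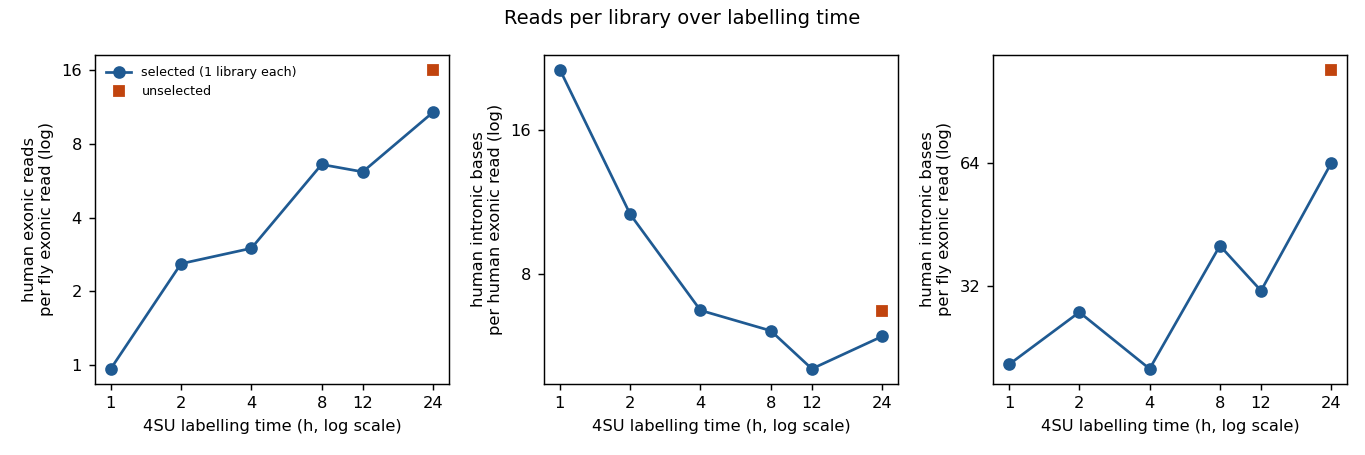
Human exonic reads per fly exonic read, human intronic bases per human exonic read and human intronic bases per fly read against 4SU labelling time, all on log axes, with a circle for each selected library and a square for the unselected 24 h library. The first measure went from 0.964 at 1 h to 10.8 at 24 h, the second from 21.4 to 5.92 and the third from 20.6 to 63.9.

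Which transcripts gain and which lose share of the labelled pool with time was asked with a trend across the 6 selected libraries, as log2 change per doubling of labelling time relative to the bulk of human genes. The steepest rise was in TECR, a reductase of very-long-chain fatty acid synthesis, with a slope of 0.85 ± 0.11 (SE). It went from 0.884 CPM, a count scaled to library size, or 3 raw counts, at 1 h to 38.5 CPM at 24 h. ERGIC3, a membrane protein of the compartment between endoplasmic reticulum and Golgi, rose from 15.3 to 195.6 CPM (slope 0.79 ± 0.06). NDUFA1, a subunit of respiratory complex I, rose from 9.14 to 94.7 CPM (slope 0.74 ± 0.06), and EIF3K, a subunit of translation initiation factor eIF3, from 50.7 to 450.1 CPM (slope 0.68 ± 0.05). Among the other steep rises were 3 genes of N-glycosylation, namely TUSC3 and DAD1, which are subunits of oligosaccharyltransferase complexes, with slopes of 0.67 and 0.65, and ALG8, a glucosyltransferase of the glycan precursor, with 0.66. STX8, an endosomal SNARE protein, had a slope of 0.71, BLVRB, a biliverdin reductase, 0.69, CPVL, a carboxypeptidase, 0.68, RNASEH2A, the catalytic subunit of ribonuclease H2, 0.66, and CFDP1 0.64.

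The steepest fall was in ZC3H12A, an endoribonuclease that degrades inflammatory mRNAs, which went from 41.9 to 3.15 CPM (slope -0.86 ± 0.08), and ID1, an inhibitor of basic helix-loop-helix transcription factors, fell from 79.3 to 5.67 CPM (slope -0.85 ± 0.08). BHLHE40, a transcriptional repressor, fell from 540.9 to 45.7 CPM (slope -0.75 ± 0.07). MYC, a transcription factor of cell growth, fell from 203 to 23.2 CPM with a slope of -0.68 ± 0.07, CTGF, a secreted matrix-associated protein, had -0.69, and INSM1, a neuroendocrine transcription factor, -0.69; with factors from fly reads these 3 slopes turned to 0.02, 0.0063 and 0.0095. MIR17HG, the host transcript of a microRNA cluster, had a slope of -0.81, SOCS3, a feedback inhibitor of cytokine signalling, -0.76, IER3, an immediate-early gene, -0.71, and PLK3, a stress-induced kinase, -0.70. RPL36A, a cytosolic ribosomal protein, went against most of its family with a slope of -0.73 ± 0.08, from 192.8 to 17.0 CPM, and the zinc-finger gene ZNF319 had -0.70. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 0.000348 for MIR17HG and lower for each of the other 23 steepest genes. With intronic factors MYC, CTGF, INSM1, IER3, PLK3, SOCS3 and ZNF319 missed the threshold (edgeR adjusted p of 0.0566 to 0.112). With fly factors ZC3H12A, ID1, BHLHE40, MIR17HG, SOCS3, IER3, PLK3, RPL36A and ZNF319 missed it (edgeR adjusted p of 0.209 to 0.926).

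On GRCh38, TECR lies on chromosome 19 from 14517085 to 14565980, ERGIC3 on chromosome 20 from 35542021 to 35557634 and NDUFA1 on chromosome X from 119871487 to 119876662. ZC3H12A lies on chromosome 1 from 37474552 to 37484379, ID1 on chromosome 20 from 31605283 to 31606515, MYC on chromosome 8 from 127735434 to 127741434 and RPL36A on chromosome X from 101390824 to 101396154. The counts cover the exons of each gene. RPL36A and other ribosomal protein genes have near-identical pseudogenes, and strand handling was not stated, so counts of such genes and of overlapping genes are uncertain.

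Of 13248 genes tested, 5839 passed at an adjusted p of 0.05 in edgeR, 2888 rising and 2951 falling. The split rests on the scaling to the bulk of genes. With factors from total intronic signal the median slope of all genes shifted to 0.36, and 6034 genes rose and 13 fell; with factors from fly reads it shifted to 0.66, and 12405 rose and 0 fell, with 12431 genes of either direction at an unadjusted p under 0.05. With library totals alone 2315 rose and 3346 fell. With hours on a linear scale 1007 genes passed, 625 rising and 382 falling, and without the 1 h library 1939 fell.

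Growth regulators of the immediate-early and AU-rich class fell together relative to the bulk of genes. Of 55 tested members 0 rose and 52 fell (0 and 53 adjusted over the list alone), with a median slope of -0.53. With intronic factors the median was -0.14, and 0 rose and 1 fell. With fly factors it turned to 0.15, and 16 rose and 0 fell. ID2, an inhibitor of basic helix-loop-helix factors, fell from 742.5 to 146.7 CPM (slope -0.51 ± 0.06), and FOS, a subunit of the AP-1 transcription factor, from 12.1 to 2.36 CPM (-0.52 ± 0.09), though both slopes turned positive with fly factors. SOX4, a developmental transcription factor, had a slope of -0.41 ± 0.08, JUN, a further AP-1 subunit, -0.34 ± 0.07, and MCL1, an anti-apoptotic protein, -0.30 ± 0.05; with fly factors the slopes of all 3 turned positive, and with intronic factors those of JUN and MCL1. With intronic factors ID2, FOS, SOX4, JUN and MCL1 missed the threshold (edgeR adjusted p = 0.379, 0.495, 0.861, 0.751 and 0.650). Without the 1 h library SOX4 and JUN missed the threshold in edgeR (adjusted p = 0.0684 and 0.0866). Zinc-finger genes of the C2H2 class, many of them transcriptional repressors, also fell: 4 of 448 rose and 291 fell (6 and 307 adjusted over the list alone), with a median slope of -0.26 that turned to 0.11 with intronic and 0.41 with fly factors. Among them ZNF711 had a slope of -0.27 ± 0.06 and ZNF24 of -0.19 ± 0.06, both positive with either of those scalings, and ZNF24 missed the threshold without the 1 h, 2 h or 12 h library (edgeR adjusted p = 0.292, 0.0662 and 0.0549). The 4 that rose, picked out after their values were seen, were ZNF428, ZNF577, ZNF638 and ZNF664. With intronic factors 33 of the 448 zinc-finger genes rose and 0 fell, and with fly factors 389 and 0. The camera test gave adjusted p = 1.01e-18 for the immediate-early list and 2.40e-18 for the zinc-finger list; adjusted p = 0.289 and 0.291 with an estimated correlation.

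Genes of the translation and energy machinery rose. Of 76 nuclear-encoded oxidative phosphorylation genes 72 rose and 0 fell, the same numbers adjusted over the list alone, with a median slope of 0.44. ATP5B and ATP5A1, the beta and alpha subunits of ATP synthase, had slopes of 0.45 ± 0.05 and 0.45 ± 0.04. Of 78 cytosolic ribosomal protein genes 70 rose and 2 fell (71 and 2 adjusted over the list alone), with a median slope of 0.42. RPS4X rose from 645.8 to 2239 CPM and RPL5 from 263.2 to 869.1 CPM, each with a slope of 0.42 ± 0.05. RPS3A, picked out after its values were seen, was the other faller beside RPL36A, at -0.40 ± 0.09. Its slope shrank to -0.0034 with intronic factors, where 1 ribosomal protein gene fell, and turned to 0.30 with fly factors. Of 34 proteasome subunits 29 rose and 0 fell, as they did adjusted over the list alone, with PSMD8 at 0.46 ± 0.06 and PSMC4 at 0.43 ± 0.06. Of 17 glycolysis genes 15 rose and 1 fell, also adjusted over the list alone. PKM, pyruvate kinase, had a slope of 0.49 ± 0.05 and GAPDH of 0.41 ± 0.05, and the faller, picked out after its values were seen, was the hexokinase HK2 at -0.21 ± 0.05, which turned to 0.16 with intronic and 0.46 with fly factors. In the camera test adjusted p was 1.18e-24 for oxidative phosphorylation, 3.58e-21 for ribosomal proteins, 4.58e-12 for the proteasome and 6.61e-06 for glycolysis; each had adjusted p = 0.289 with an estimated correlation.

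Further housekeeping groups also rose. Of 29 cytoskeleton and chaperone genes 25 rose and 0 fell (26 and 0 adjusted over the list alone), among them ACTB, cytoplasmic beta-actin, with a slope of 0.31 ± 0.06, and the chaperone HSP90AB1 with 0.31 ± 0.05. Of 30 lysosomal genes 22 rose and 2 fell (23 and 2 adjusted over the list alone). PSAP, the precursor of sphingolipid activators, had 0.51 ± 0.05 and the membrane protein CD63 had 0.48 ± 0.05, and the fallers, picked out after their values were seen, were NAGLU and SGSH, both enzymes of heparan sulfate breakdown, whose slopes of -0.36 and -0.20 turned positive with intronic and fly factors. Of 34 translation factors 24 rose and 0 fell (27 and 1 adjusted over the list alone), with EEF2, the ribosomal translocase, at 0.27 ± 0.06 and EIF4G1, an initiation scaffold, at 0.19 ± 0.05. Of 20 cytosolic aminoacyl-tRNA synthetases 17 rose and 0 fell (18 and 0 adjusted over the list alone), with EPRS at 0.35 ± 0.06 and NARS at 0.26 ± 0.05. Of 28 S-phase genes 13 rose and 2 fell, also adjusted over the list alone. MCM7 and MCM4, subunits of the replicative helicase, had 0.25 ± 0.05 and 0.22 ± 0.05. The fallers, picked out after their values were seen, were the replication-onset regulators CCNE1 and CDT1, whose slopes of -0.42 and -0.24 turned positive with fly factors. With intronic factors that of CDT1 also turned positive, that of CCNE1 was -0.07, and 0 S-phase genes fell. The camera test gave adjusted p = 3.25e-10 for cytoskeleton and chaperones, 2.08e-07 for both lysosomal genes and translation factors, 1.58e-06 for the synthetases and 0.00487 for S-phase genes; each had adjusted p = 0.289 with an estimated correlation. EIF4G1 missed the threshold without the 1 h library (edgeR adjusted p = 0.0885).

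In 3 stress and noncoding lists most members that passed fell relative to the bulk of genes. With intronic or fly factors 0 members of these lists fell. Of 21 genes of the unfolded-protein and integrated stress response 3 rose and 13 fell (3 and 14 adjusted over the list alone), with a median slope of -0.26 that turned to 0.11 with intronic and 0.41 with fly factors. ATF4, the transcription factor of this response, had -0.25 ± 0.05, a slope that turned positive with both of those scalings, whereas its serine synthesis members PSAT1 and PHGDH, and the asparagine synthetase ASNS, rose; PHGDH and ASNS were picked out after their values were seen. Of 22 p53 targets 1 rose and 10 fell, also adjusted over the list alone, with a median slope of -0.12 that turned to 0.24 and 0.54. AEN, an apoptosis-enhancing nuclease, had -0.36 ± 0.05 and MDM2, the ubiquitin ligase of p53, -0.31 ± 0.05, both positive with either of those scalings, and the riser, picked out after its values were seen, was the pro-apoptotic BAX. Of 19 snoRNA host and growth-linked transcripts 1 rose and 11 fell, also adjusted over the list alone, with a median of -0.19 that turned to 0.19 and 0.50. SNHG16 had -0.37 ± 0.06 and SNHG1 -0.25 ± 0.08, both positive with either scaling, and the riser, picked out after its values were seen, was DANCR. In camera, adjusted p was 0.00368 for the stress response, 0.0151 for p53 targets and 0.0386 for snoRNA hosts; adjusted p = 0.311, 0.289 and 0.576 with an estimated correlation. The snoRNA host list missed the threshold without the 1 h and without the 8 h library (camera adjusted p = 0.911 and 0.0579), as did SNHG1 (edgeR adjusted p = 0.950 and 0.0538). The list also missed it with intronic factors (camera adjusted p = 0.0798) and in fry (adjusted p = 0.154).

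The remaining 8 lists tested did not pass in camera. Their counts of risers and fallers below are relative to the bulk of genes. With intronic or fly factors 0 of their members fell. Of 24 cholesterol genes 9 rose and 5 fell, also adjusted over the list alone. Among the fallers were IDI1 (-0.16 ± 0.05) and, picked out after their values were seen, MSMO1 (-0.23 ± 0.05) and INSIG1 (-0.20 ± 0.06), whose 3 slopes turned positive with intronic and fly factors. IDI1 missed the threshold without the 2 h, 12 h or 24 h library (edgeR adjusted p = 0.0648, 0.0614 and 0.0501). Of 10 nuclear long noncoding RNAs 1 rose and 5 fell, also adjusted over the list alone, with a median of -0.17 that turned to 0.20 with intronic and 0.51 with fly factors. NEAT1, the scaffold of paraspeckles, had -0.43 ± 0.09, which missed the threshold with intronic factors (edgeR adjusted p = 0.724) and turned positive with fly factors, and MALAT1, a nuclear speckle RNA, -0.34 ± 0.08, which turned positive with both; without the 1 h library they missed the threshold (edgeR adjusted p = 0.0781 and 0.268). NORAD had -0.15 ± 0.05, positive with intronic and fly factors, and missed the threshold without the 1 h, 2 h or 12 h library (edgeR adjusted p = 0.176, 0.0760 and 0.0585). Picked out after their values were seen, the other fallers were MIAT and KCNQ1OT1, with slopes of -0.56 and -0.37 that turned positive with fly factors, that of KCNQ1OT1 also with intronic factors, and the riser was OIP5-AS1 (0.31). Splicing regulators went both ways relative to the bulk of genes. Of 32 SR protein and hnRNP genes 7 rose and 7 fell, also adjusted over the list alone. With intronic factors 18 rose and 0 fell, and with fly factors 31 and 0. SRSF2 had -0.28 ± 0.05, positive with intronic and fly factors, and HNRNPA2B1 0.20 ± 0.06. SRSF2 missed the threshold without the 1 h library and HNRNPA2B1 without the 24 h library (edgeR adjusted p = 0.0519 and 0.116). Of 50 mRNA decay factors 11 rose and 10 fell, also adjusted over the list alone. Their median slope was -0.02 and their mean 0.01, and camera's direction was up. With intronic factors 25 of them rose and 0 fell, and with fly factors 50 and 0. LSM14A, a translational repressor of P-bodies, had 0.16 ± 0.04 and missed the threshold without the 1 h library (edgeR adjusted p = 0.0926).

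Relative to the bulk of genes, few cell cycle genes of G2/M passed. Of 26 such genes 5 rose and 0 fell, also adjusted over the list alone. The 5, picked out after their values were seen, were NUSAP1 (0.25), TPX2 (0.24), CCNB2 (0.24), BUB1 (0.21) and BIRC5 (0.16), all mitotic regulators. With intronic factors 18 of the 26 rose and 0 fell, and with fly factors 26 and 0. PRC1, a spindle midzone protein, had a slope of 0.08 ± 0.04 and did not pass (edgeR adjusted p = 0.163). It passed with intronic and fly factors (edgeR adjusted p = 0.0249 and 7.91e-09). Of 5 replication-dependent histone genes HIST1H2BK rose (0.37 ± 0.07) and 0 fell, also adjusted over the list alone. Of 11 neuronal genes 4 rose and 0 fell (3 and 0 adjusted over the list alone), among them UCHL1, a ubiquitin hydrolase, at 0.48 ± 0.05, the adhesion molecule NCAM1 at 0.29 ± 0.05 and the enolase ENO2 at 0.15 ± 0.06. ENO2 missed the threshold with library totals (edgeR adjusted p = 0.101), in limma-voom (adjusted p = 0.0513) and without the 2 h, 8 h, 12 h or 24 h library (edgeR adjusted p = 0.167, 0.0681, 0.145 and 0.204). The last, picked out after its values were seen, was the intermediate filament INA (0.25). Of 5 fibroblast and endothelial markers ACTA2, smooth muscle actin, rose (0.53 ± 0.10), from 2.36 to 8.98 CPM, and 0 fell, also adjusted over the list alone. In camera, adjusted p was 0.0842 for neuronal genes, 0.0842 for nuclear long noncoding RNAs, 0.130 for cholesterol genes, 0.150 for G2/M genes, 0.203 for histones, 0.282 for fibroblast and endothelial markers, 0.577 for decay factors and 0.753 for splicing regulators. Of these, cholesterol genes passed without the 24 h library (camera adjusted p = 0.0396), nuclear long noncoding RNAs without the 2 h or 24 h library (0.0393 and 0.0394 in camera) or with intronic factors (0.0462), and neuronal genes and the fibroblast and endothelial markers without the 1 h library (0.0328 and 0.0470 in camera). In fry, which tests each list on its own, histones (adjusted p = 0.00775), neuronal genes (0.0167) and decay factors (0.0179) passed. Of the blood cell markers 2 were tested and 0 passed, with or without adjustment over the list alone, and of the mitochondrially encoded mRNAs 0 were listed under the symbols sought. With an estimated correlation 0 of the 22 lists tested passed in camera, against 14 with the preset one.

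**Figure D2:**
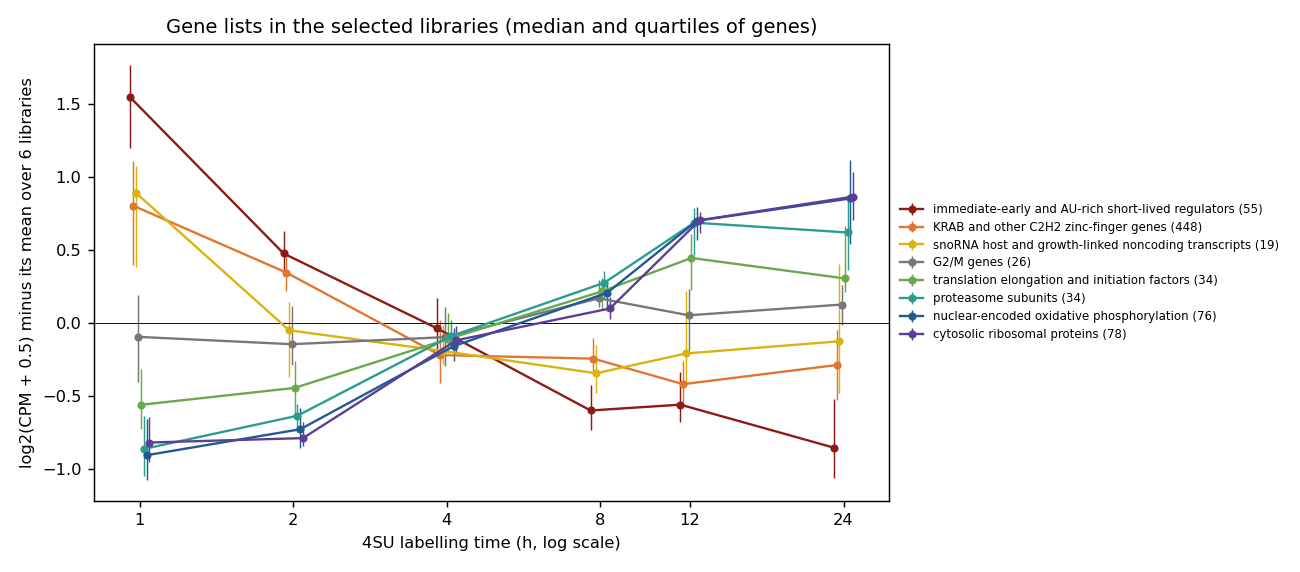
Median over the genes of each list of log2(CPM + 0.5) minus its mean over the 6 selected libraries (points, with quartiles as bars) against labelling time on a log axis, with the number of genes in brackets. The immediate-early list went from 1.55 at 1 h to -0.85 at 24 h and ribosomal proteins from -0.82 to 0.87, relative to the bulk of genes; with fly factors the immediate-early slope turned positive.

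Half-lives were fitted per gene from the rise of exonic counts over intronic signal towards a plateau. Transcripts of oxidative phosphorylation genes had a median half-life of 8.50 h (76 genes) and those of ribosomal proteins 8.27 h (78 genes), with RPS4X at 8.65 h and RPL5 at 8.13 h. Glycolysis genes had a median of 6.45 h, cytoskeleton and chaperone genes 6.32 h, proteasome subunits 6.21 h, lysosomal genes 5.40 h, aminoacyl-tRNA synthetases 4.29 h and translation factors 4.03 h. These hours depend on the scale. With fly reads the medians of oxidative phosphorylation, ribosomal protein, glycolysis, and cytoskeleton and chaperone genes, like RPS4X and RPL5, lay at the upper bound of 200 h, with the proteasome at 192 h, lysosomal genes at 55.9 h, synthetases at 20.1 h and translation factors at 17.6 h. With library totals the 8 lay between 1.01 and 2.12 h. That scale sets the human sum of every library equal and so removes the overall rise that the fit relies on. Hours with library totals, here and below, are therefore not estimates of half-life and show only the order of genes. On each of the 3 scales the 8 lists lay above the central 95% of 10000 random lists of the same size and expression. The scales divide the same counts by 1 factor per library that all genes share, so they are not independent checks. Immediate-early regulators had a median at the lower bound of the fit, 0.05 h. The stress response list had 0.682 h, zinc-finger genes 0.715 h, snoRNA hosts 0.813 h and nuclear long noncoding RNAs 0.979 h. These 5 lay below the central 95% of random lists. With fly reads they had 0.603, 2.23, 2.05, 2.95 and 3.18 h, the last then inside the random range, and p53 targets, at 3.51 h, lay below it. With library totals 6298 of 13126 genes lay at the bound of 0.05 h. The medians of these 5 lists and of splicing regulators (percentile 1.39) were then at that bound. So was the low end of their random lists, so their place among these cannot be judged. Cholesterol genes (0.751 h, percentile 99.5) lay above the central 95% with library totals. On the intronic scale the 7 lists inside the central 95% were p53 targets (1.38 h), decay factors (1.92 h), splicing regulators (2.05 h), G2/M genes (2.47 h), S-phase genes (2.71 h), neuronal genes (2.86 h) and cholesterol genes (2.93 h).

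Among well-counted genes with a narrow fit, the longest half-lives were those of FSTL1, a secreted glycoprotein, at 12.1 h (95% interval 6.63 to 22.0), UQCRB, a subunit of respiratory complex III, at 11.9 h (6.80 to 20.9), and B2M, the light chain of MHC class I, at 10.3 h (5.30 to 20.0). ATP6AP2, an accessory protein of the proton pump, had 9.96 h, GGH, a folate hydrolase, 9.85 h, HSD17B4, a peroxisomal enzyme, 9.11 h, QPCT, a glutaminyl cyclase, 9.01 h, and PRDX3, a mitochondrial peroxiredoxin, 8.81 h. With fly scaling these 8 lay at the upper bound of 200 h, with library totals between 1.82 and 2.45 h, and without the 24 h library UQCRB moved to 25.1 h, FSTL1 to 18.4 h, B2M to 16.6 h and QPCT to 15.4 h. The shortest were DYRK1A, a protein kinase, at 0.22 h (0.151 to 0.320), the ubiquitin ligase adaptor KLHL11 at 0.251 h, the zinc-finger genes ZNF264 at 0.270 h, ZNF284 at 0.378 h and ZNF180 at 0.379 h, STOX2 at 0.291 h, ZSCAN12 at 0.375 h and RUNX2, a bone transcription factor, at 0.379 h. On this scale they lie below the earliest time point, but with fly scaling they had 1.17 to 1.38 h, with library totals 0.05 h, and without the 1 h library ZNF264 moved to 0.447 h and the other 7 to the bound of 0.05 h. ACTB had 4.95 h (1.68 to 14.6) and GAPDH 7.58 h (2.31 to 24.9), which moved to 11.6 and 21.2 h without the 24 h library; JUN had 0.362 h (0.0591 to 2.22), 0.543 h without the 1 h library, FOS 0.206 h with an interval too wide to place it, and MYC lay at the bound of 0.05 h. With fly scaling ACTB had 33.6 h, GAPDH the bound of 200 h, JUN 1.48 h and FOS 0.721 h, and MYC stayed at its bound; with library totals ACTB had 1.28 h, GAPDH 1.88 h and the other 3 the bound of 0.05 h.

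DYRK1A lies on chromosome 21 from 37365573 to 37526358, KLHL11 on chromosome 17 from 41853545 to 41865431, FSTL1 on chromosome 3 from 120392293 to 120451253, UQCRB on chromosome 8 from 96225920 to 96235634 and B2M on chromosome 15 from 44711487 to 44718877 of GRCh38. Over 13126 genes the median half-life was 1.91 h (quartiles 1.10 and 3.20 h). It was 5.59 h with fly reads as the scale, 0.186 h with library totals and 1.26 h with the plateau fixed at the unselected library.

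**Figure D3:**
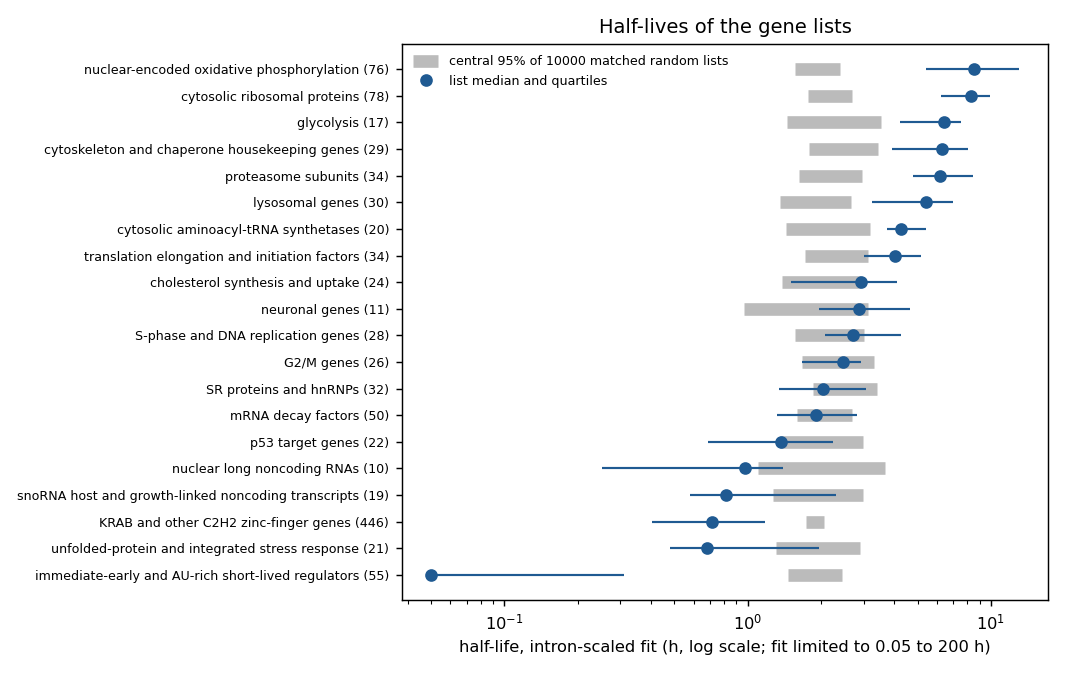
Median half-life of each gene list in the intron-scaled fit (points, with quartiles as bars, hours on a log axis, genes in brackets) beside the central 95% of 10000 random lists of like size and expression (grey). Oxidative phosphorylation and ribosomal protein genes sit at 8.50 and 8.27 h, and the immediate-early list at the lower bound of 0.05 h; with fly reads as the scale the first 2 lay at the upper bound of 200 h and the last at 0.603 h.

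The deposit also held the authors' half-lives from an intron-based normalization and from another, unstated one. In the authors' deposited tables ACTB had 4.95 h with the intron-based normalization and 55.1 h with the other, HSP90AB1 5.25 and 218 h, and EEF2 4.24 and 23.4 h. For the short-lived JUN the authors' deposited tables gave 0.769 and 3.19 h, for MDM2 0.929 and 2.00 h and for ID2 0.382 and 0.610 h. GAPDH, RPS4X, RPL5 and PRDX3 had a value only in the authors' deposited intron-based table, of 7.58, 9.02, 7.76 and 10.4 h. Over the 11673 genes with both values the authors' deposited medians were 2.14 and 7.48 h, the other value was the longer in 100% of them, and the median ratio was 3.40 (quartiles 2.35 and 5.49). Spearman's rho between the authors' deposited tables was 0.88 across genes, which are not independent replicates. Without the 24 h library the authors' deposited median in the other table went from 7.42 to 3.87 h. The intron-scaled fit described above had a Spearman's rho of 0.979 across 12834 genes with the authors' deposited intron-based values and a median ratio to them of 0.821. The fly-scaled fit had a higher rho with them, 0.995, and a median ratio of 2.38. Across 11240 genes with a value from the authors' other normalization, the intron-scaled fit had a rho of 0.797 and a median ratio of 0.228. There the fly-scaled fit had a rho of 0.880 and a median ratio of 0.744.

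Whether selection itself alters the pool was asked at 24 h, where a selected and an unselected library were made after the same labelling. Ribosomal protein transcripts were lower after selection, with a median log2 ratio of selected to unselected of -0.57 over 77 genes, 13 of which were more than 2-fold lower. RPL35 had -1.82 (95% counting interval -1.93 to -1.71) and RPL36 -1.59 (-1.70 to -1.48). Oxidative phosphorylation genes had a median of -0.36 over 73 genes, 3 of them more than 2-fold lower, although ATP5A1 had 0.31 and ATP5B 0.15. Both medians lay below all 10000 random lists of the same size and expression. MALAT1 had -1.55, MDK, a heparin-binding growth factor, -1.76, MIF, a cytokine, -1.58, and ANKRD36C -1.67, and the genes listed as RNR1 and RNR2 had -2.30 and -1.61. The highest of the genes named by the rule were ADAMTS17, a secreted metalloprotease, at 0.97 (0.54 to 1.41), LINC01355 at 0.86, DNASE1L1 at 0.85, NMNAT1, an enzyme of NAD synthesis, at 0.80, ANO10 at 0.79, CPT1A, which controls fatty acid entry into mitochondria, at 0.78, the mitochondrial peptidase MIPEP at 0.76 and SLC35E2 at 0.71.

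Of 9776 genes with a mean of at least 10 CPM, 1 was more than 2-fold higher and 47 more than 2-fold lower in the selected library, and for 1 and 18 of them the counting interval lay wholly beyond 2-fold. With a minimum of 1 CPM 354 genes passed 2-fold, and with 50 CPM 24 did. These ratios compare 2 libraries, not conditions, and the intervals cover counting error only. Translation factors (-0.05) and lysosomal genes (-0.06) lay at percentiles 1.39 and 2.74 of random lists. The remaining 16 lists with enough genes lay between percentiles 4.88 and 96.7, with the immediate-early list at -0.01 and zinc-finger genes at -0.01. RPL35 lies on chromosome 9 from 124857880 to 124861981, RPL36 on chromosome 19 from 5674947 to 5691876, MALAT1 on chromosome 11 from 65497688 to 65506516 and ADAMTS17 on chromosome 15 from 99971589 to 100342005 of GRCh38.

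**Figure D4:**
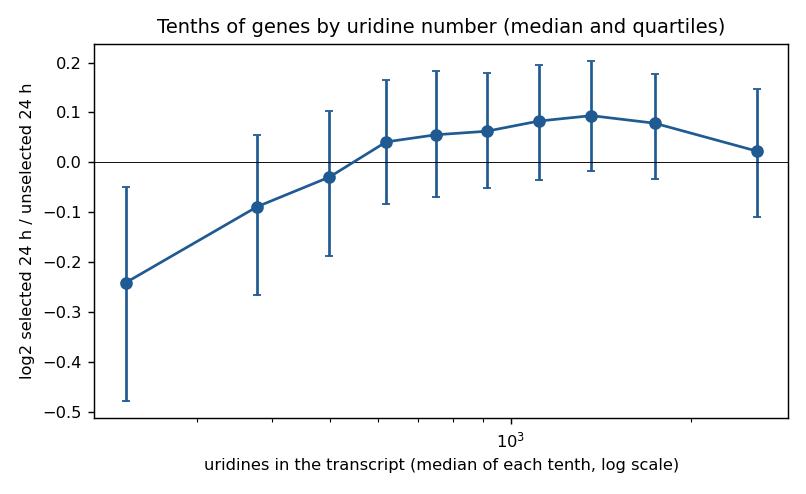
Log2 ratio of the selected to the unselected 24 h library (median and quartiles) in 10 groups of genes of like size ordered by the number of uridines in the annotated transcript (log axis). The median went from -0.24 in the group with 52 to 310 uridines to 0.09 in that with 1230 to 1518, and was 0.02 in the highest group.

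Genes with few uridines were lower in the selected library. In 10 groups of like size, over 9705 genes with an annotated transcript, the median log2 ratio was -0.24 for genes with 52 to 310 uridines, 0.09 for those with 1230 to 1518 and 0.02 in the highest group. Ribosomal protein genes have short transcripts with a median of 206 uridines, and other genes with like numbers had a median of -0.25. Beyond that value the ribosomal protein genes were lower by a median of -0.39, in 64 of 75 genes, and oxidative phosphorylation genes by -0.07, in 48 of 71.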

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

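The tests of fly against intronic scaling and of other orders of the time points were chosen only after the results were seen; the tests of uridine number and of incomplete labelling were not.

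Reads of yeast RNA, which enter none of the comparisons above, were present in every library, and the unselected library is the only one without selection to set them against. There were 895 at 1 h, 552 at 2 h, 1166 at 4 h, 439 at 8 h, 512 at 12 h and 346 at 24 h, and 31322 in the unselected library. Relative to fly reads that was 0.0251% at 1 h, 0.0547% at 24 h and 8.27% in the unselected library. Every selected library thus held far less yeast RNA per fly read than the unselected one. The role of the yeast RNA is not stated, and the cause was not tested. Fly introns, also outside the comparisons, gave 0.612, 0.645, 0.621, 0.746, 0.684 and 0.814 bases per fly exonic read from 1 to 24 h and 1.09 in the unselected library.

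Half-lives were longer when fly reads set the scale than when intronic signal did, with medians of 5.59 and 1.91 h, a ratio of 2.93. Intronic bases per fly read, relative to 1 h, were 1.34, 0.976, 1.95, 1.51 and 3.10 at 2, 4, 8, 12 and 24 h. No single library accounts for the whole gap in these tables, since the lowest ratio with 1 library left out was 1.93, without the 24 h library. Part of the gap thus rests on the 24 h library. Introns that overlap other genes or exons do not account for the whole gap either, since without them the ratio was 2.66. Whether the fly amount per library or the intronic signal of the cells changed with labelling time stays open, and no biological explanation was tested.

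In the 24 h pair, the ratio of selected to unselected RNA followed uridine number. Within 3 groups of like size by half-life, Spearman's rho across genes was 0.06, 0.23 and 0.51 from short to long, with a median of 0.234, so limited capture of transcripts with few uridines may account for part of the pattern. Incomplete labelling of long-lived RNA would lower the ratio with half-life, but within 3 groups by uridine number rho was -0.23, 0.04 and 0.12, with a median of 0.0436, which argues against it as the cause across genes. In the group with the fewest uridines, which holds most ribosomal protein genes, it stays open. Uridine number also rose with transcript length, from a median of 1022.5 nt in the lowest of 10 groups to 9272 nt in the highest. An effect of uridine number therefore cannot be told apart from one of length by these groups. Within 3 groups by transcript length, rho with the fraction of uridines was 0.40, 0.26 and 0.04 from short to long.

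The number of genes with a trend was set against other orders of the time points. The real order called 5839 genes, the highest of the others 5301, and 1 of the 100 orders, the real one, gave as many. This argues against a chance order of the libraries, at a resolution of 1 in 100. It cannot tell labelling time from any other difference between the libraries that follows the same order.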

How the results depend on the processing

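Scalings with introns that overlap no other gene or no exon, fly reads with linear residuals, fly-scaled list half-lives, the fit without the most abundant RNA and the intron trends without each library were chosen only after the data were seen. No paired analysis was possible because each group has 1 library. Unless named, the cause of a change was not tested.

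Calls of rising and falling genes depend on the scaling. Intronic factors gave 6034 rising and 13 falling, fly factors 12405 and 0 of 12405 called, and linear hours 625 and 382 of 1007, while library totals, DESeq2 factors or test, limma-voom, ranks and other filters stayed within 1.5 times. Without each library in turn 4103 to 6643 genes were called, 2003 to 3258 rising and 1939 (without 1 h) to 3385 falling. With an estimated correlation 0 lists passed, and 13 to 16 without each library; the splicing regulators, with camera adjusted p of 0.114 to 0.944 without each library, turned down without 2 h (0.907) and 24 h (0.944). Of 68 named genes 32 missed the threshold in the same direction with linear hours, 11 with intronic factors, 9 with fly factors and 10 without 1 h.

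With intronic factors these slopes were reversed in sign: AEN 0.0052, ATF4 0.13, IDI1 0.20, JUN 0.0483, MALAT1 0.0433, MCL1 0.0753, MDM2 0.0513, NORAD 0.21, SNHG16 0.0184, SNHG1 0.14, SRSF2 0.12, ZNF24 0.18 and ZNF711 0.0879. None of them passed (edgeR adjusted p from 0.189 for NORAD to 0.978 for AEN). With fly factors the reversed slopes were AEN 0.31, ATF4 0.43, CTGF 0.0063, FOS 0.16, ID2 0.17, IDI1 0.51, INSM1 0.0095, JUN 0.34, MALAT1 0.36, MCL1 0.37, MDM2 0.36, MYC 0.0199, NEAT1 0.26, NORAD 0.52, SNHG16 0.32, SNHG1 0.45, SOX4 0.28, SRSF2 0.42, ZNF24 0.48 and ZNF711 0.40. Of these, CTGF, FOS, ID2, INSM1 and MYC missed the threshold (edgeR adjusted p from 0.161 for ID2 to 0.963 for CTGF). The shift of all slopes by the factors shows the cause.

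The median half-life of 1.91 h was 1.95 with the steadiest introns, 5.59 with fly reads (7.08 with linear residuals), 0.186 with library totals, 2.07 with a background, 1.26 with a fixed plateau, 1.53 with linear residuals, 2.00 and 1.87 with count minimums of 500 and 10, 1.97 and 2.10 without introns that overlap other genes or also exons, and 1.44 to 2.20 without each library. By percentile, list medians stood outside the central 95% of random lists in 13 of 20 lists, 13 with fly reads and 10 with library totals. The last count includes the splicing regulators, whose median was tied with random lists at the bound of 0.05 h. The authors' deposited tables differed 3.26-fold within 1 to 24 h and 3.65-fold from 500 counts on. In the 24 h pair 354 genes passed 2-fold from 1 CPM and 24 from 50 CPM, among 13098 and 5094 genes kept. The intronic ratio kept its rho of -0.94 in the sets tried. In simulated data with 200 changed genes 20% of slopes of 0.2 were recovered, which does not give the share missed in the real data, where far more genes passed. What depth alone limits was not tested. Half-lives are limited by the sampled 1 to 24 h.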

Other observations

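The tests of single introns and the rule that named them were partly chosen after the result was seen, namely the fits without each library and the choice of named introns; the predictions for overlap and host gene were not.

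Of 190 introns of ribosomal protein genes 6 rose and 45 fell (23.7%) in their share of the intronic signal with labelling time in limma, and of 155 introns of SR protein and hnRNP genes 2 rose and 11 fell (7.10%). Smaller lists had falling shares above that of SR protein and hnRNP genes. Of 56 introns of cholesterol genes 1 rose and 6 fell (10.7%). Lysosomal genes had 3 rising and 4 falling of 47 (8.51%), and glycolysis genes 2 and 3 of 42 (7.14%). Of all 23149 introns tested 4.35% rose and 1.85% fell. No test of gene groups was run on introns, and introns of 1 gene are not independent. Introns were named only if they overlap no annotated exon or other gene, have a mean of at least 2000 bases and lie in named genes. Among those that passed, the steepest rise was in PIEZO1, a mechanosensitive ion channel, in a 35421 bp intron on chromosome 16 from 88749480 to 88784900 of GRCh38. Its signal went from 510 bases at 1 h to 5748 at 24 h (slope 0.93 ± 0.08). QSOX2, a sulfhydryl oxidase, had a rising intron on chromosome 9 from 136226875 to 136245475 (slope 0.67 ± 0.09), and TMOD1, an actin-capping protein, on chromosome 9 from 97569038 to 97591290 (0.63 ± 0.09). Falling introns lay in KLF15, a transcription factor, on chromosome 3 from 126343896 to 126351840 (-0.53 ± 0.10), EWSR1, an RNA-binding protein, on chromosome 22 from 29287135 to 29288605 (-0.42 ± 0.07), and YBX1, a cold-shock domain protein, on chromosome 1 from 42697263 to 42700780 (-0.40 ± 0.07), whose exonic counts rose with a slope of 0.41.

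Of 23149 introns tested with limma, 1008 rose and 428 fell at an adjusted p of 0.05. Without the 1 h library 312 rose and 180 fell, without 2 h 665 and 116, without 8 h 546 and 157, without 12 h 407 and 141, without 4 h 1615 and 910, and without 24 h 1014 and 258. The rising introns had a median length of 6290.5 bp, against 3277 bp for all tested introns and 2340 bp for falling ones.

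Reads of exons or other genes inside the interval could produce a rise. Of the placed rising introns 77.9% overlapped an annotated exon or another gene, against 66.2% of all tested introns and 71.0% of falling ones. The value for rising introns lay between the bounds set for and against this explanation. It therefore cannot be told apart from other sources of the rise. Signal that follows the mature RNA of the host gene might also rise, but the correlation of intron and exonic slopes over the rising introns was 0.103 (Spearman, across introns), just above the bound set against it, so this too stays open. No biological explanation was tested.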
